A study of Mus musculus with 28 samples.

How the data were processed

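Populations were sorted by flow cytometry from back skin of mice at postnatal day 5. Per the labels' protocols, total RNA of samples with an RNA integrity number of at least 8.8 was taken forward, 6 ng was reverse transcribed and amplified, and libraries were made from 100.0 ng of amplified cDNA. Amplification from so little RNA limits how well low genes are measured. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled per library) with a column for each of the 28 libraries. The submitters' processing notes name TopHat2 2.0.3, Bowtie2, Cufflinks 2.1.1 and the mouse genome build mm10, and further steps, such as the annotation and filters, are not given in the sources used here. Each column was assigned to a sample by its name, and groups and replicate numbers came from the sample labels.

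The table held 23235 rows, of which 220 were identical to another row and were dropped. Of the 23015 kept, 64 shared a symbol with another row and 170 joined several gene names, so that their values cannot be divided among those genes. Gene positions printed here are those of the RefSeq genes of GRCm38.p6 (mm10) with the same symbol, given from the first base counted as 1. The start in the deposited table lay 1 below the RefSeq start for 8942 of 18620 matched protein-coding genes and was equal to it for 646. Deposited starts were therefore raised by 1, but the deposited positions are not printed and can differ from those of RefSeq. The deposited FPKM were used without further scaling. Totals, from 285980.6 to 515224, are not depths. Upper quartiles lay between 10.31 and 11.08 FPKM in all libraries, so the table may already have been scaled between libraries, which the sources used here do not state. Where whole fragments are counted, low values of a library are multiples of 1 fragment. Such a step closed within 0.06 on the log2 scale in 143 of 378 pairs of libraries (37.8%), so no depth was recovered and no counting interval can be given. Genes that share sequence with near-identical copies, such as keratin-associated protein and haemoglobin genes, are uncertain, and strand was not stated, so overlapping antisense genes cannot be separated.

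Genes with at least 1 FPKM in at least 2 libraries (15052) were tested on log2(FPKM + 1), with a pseudocount of 1. The fit was made with limma 3.58.1 in R 4.3.3 on all 28 libraries, with 1 mean per population and no other term, and empirical Bayes with a trend (14 residual and 5.7 prior degrees of freedom). All populations thus shared 1 estimate of spread per gene, since each had 2 libraries. P-values were adjusted by the Benjamini-Hochberg method within each of 8 comparisons. Signature genes were called higher in 1 of the 8 populations of the K14-H2BGFP line than in each of the other 7, so that mouse line and population were not mixed. Enrichment of ligands and receptors in signatures was tested with Fisher's exact test, two-sided, against all genes tested, with adjustment over 16 tests. The papilla subtype and Sox9-GFP comparisons were each made within 1 mouse line.

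The labels give the same replicate numbers in each population without saying what a number marks. Deviations of same-numbered samples from their population means correlated at 0.057 to 0.275 in the 28 pairs of the K14-H2BGFP line (27 over 0.1), at 0.283 in the Crabp1-GFP, 0.285 in the Sox2-GFP and 0.071 in the K14-RFP Sox9-GFP line, and at 0.038 to 0.291 between lines. In the K14-H2BGFP, Sox2-GFP and K14-RFP Sox9-GFP lines the levels of Xist and of the Y-linked gene Ddx3y differed between replicates 1 and 2 in the same direction in every population of a line. Same-numbered samples of these 3 lines were therefore read as paired by animals of the same sex makeup, which does not show that they were the same animals. This reading was made after the fits with and without the block had been compared, so the fit without it, fixed beforehand, was kept. In the Crabp1-GFP line Xist was near 0 in both replicates and pairing stays open, although all 4 of its libraries correlated best with a same-numbered library, for 3 of them one of the Sox2-GFP line. Values with the replicate number within each line as a block are given beside a result where the block changed a call or moved a total count over 1.5 times, and for both papilla subtype comparisons.

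The gene lists, comparisons, tests and the rule for named genes were fixed before the data were examined. There were 17 pathway lists and 11 lists of markers of other cell types, drawn from textbook knowledge, and 131 list tests were run with camera in limma, with a preset correlation of 0.01 and again with the correlation estimated, adjusted within each comparison. Some genes belong to more than 1 list. Named genes were those of the sorting gates, the 5 with the largest higher and the 5 with the largest lower log2 change among called genes with a mean of at least 5 FPKM in the higher population (leaving out predicted names, small RNAs and joined rows), and of each pathway list the called members with the largest changes, 2 per direction, or the 2 with the smallest p where none was called. In signatures they were, with the same minimum and names left out, the 5 genes with the largest smallest change over the other populations and the first 3 ligands and receptors. Other genes printed are members of these lists or signatures named as examples, or are said to be chosen after their values were seen. Some genes counted in lists or signatures are not reported here by name.

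The scripts were tested on simulated data with 50 genes changed by each of 4 sizes on the 15052 genes of each comparison. Changed genes were drawn only from those at 5 or more on the log2(FPKM + 1) scale in the second population, so recovery of lower genes was not tested. Noise was independent between libraries, with 1 spread per gene in all populations. A log2 change of 1 was recovered for 14% (DP against DF) to 38% (TAC against Mx), and a change of 2 for 78% (ORS against Epi) to 94% (DP against DF). Of all calls, 2.44% (TAC against Mx) to 9.09% (G-DP against AA/ZZ-DP) were unchanged genes, a share that depends on how many genes are changed. In G-DP against AA/ZZ-DP 15 unchanged genes were called in the simulation, beside 76 calls in the real data. Alternatives tried were pseudocounts of 0.1 and 5, a filter at 5 FPKM and none, median-of-ratios scaling, quantile normalization, no trend, the libraries compared alone, a block for the replicate number, and leaving out each library. Counts without signature genes of other populations and, for HF-SC against HF-ORS, without those of Epi were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.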

Results

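Gene expression was measured in 14 cell populations sorted by flow cytometry from mouse back skin at postnatal day 5, when the first hair follicles grow down into the dermis. Each population had 2 libraries, 28 in all. Skin carrying a K14-H2BGFP transgene, which marks keratinocyte nuclei, and Lef1-RFP gave 8 populations. Epi was the GFP-positive fraction of the epidermal preparation, ORS (outer root sheath) the brightly GFP-positive cells of the dermal preparation, and Mx (matrix) the dimly GFP-positive cells. TAC, described by the submitters as Shh-expressing matrix progenitors, combined dim GFP with Lef1-RFP. Mc (melanocytes) were Lef1-RFP-positive and CD117-positive, CD117 being the Kit receptor. DF (dermal fibroblasts) were Lef1-RFP-positive and lacked CD117 and integrin alpha 9, DP (dermal papilla) had high integrin alpha 9, and Neg held a mixture of marker-negative cells. Dermal papillae were further divided by follicle type with a Sox2-GFP reporter (ZZ-DP, zigzag, GFP-negative, and G/AA-DP, guard and awl/auchene, GFP-positive) and with a Crabp1-GFP reporter (G-DP, guard, GFP-negative, and AA/ZZ-DP, GFP-positive). A K14-RFP Sox9-GFP line gave HF-SC, the precursors of bulge stem cells (Sox9-GFP-positive), and HF-ORS, the rest of the outer root sheath (Sox9-GFP-negative).

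Values are FPKM, written as mean ± SD of the libraries of a population (n = 2), and log2 changes are differences of log2(FPKM + 1) ± SE, which understate the change of low genes. FPKM sums per library ran from 285980.6 to 515224, and 10951 to 12497 genes reached 1 FPKM. Sequencing depth is unknown, so no interval for counting error is given. The Pearson correlation across genes between replicates, which are not independent measurements, ran from 0.884 in G-DP to 0.966 in ORS. All 8 papilla subtype libraries, and DP replicate 2, correlated better with a same-numbered library of another papilla sort than with their own replicate (G-DP replicate 1 at 0.942 with AA/ZZ-DP replicate 1), which none of the other libraries did. The labels do not say whether replicates came from separate animals. In 3 of the 4 mouse lines genes of the sex chromosomes differed between replicates 1 and 2 (in HF-SC, Xist was at 472 and 0.97), so these replicates did not come from 1 pool of animals. P-values of the Crabp1-GFP line rest on a spread pooled over all 28 libraries, most of them of other lines. The spread between its own samples may be technical. A gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in limma, among 15052 genes tested. Widely used genes were listed at exactly 0 in some libraries (Malat1 in 10 of 28). An exact 0 can therefore be a failed estimate, so a gene at 0 is described only as listed at 0, and calls that rest on such a 0 are included in the counts.

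**Figure D1:**
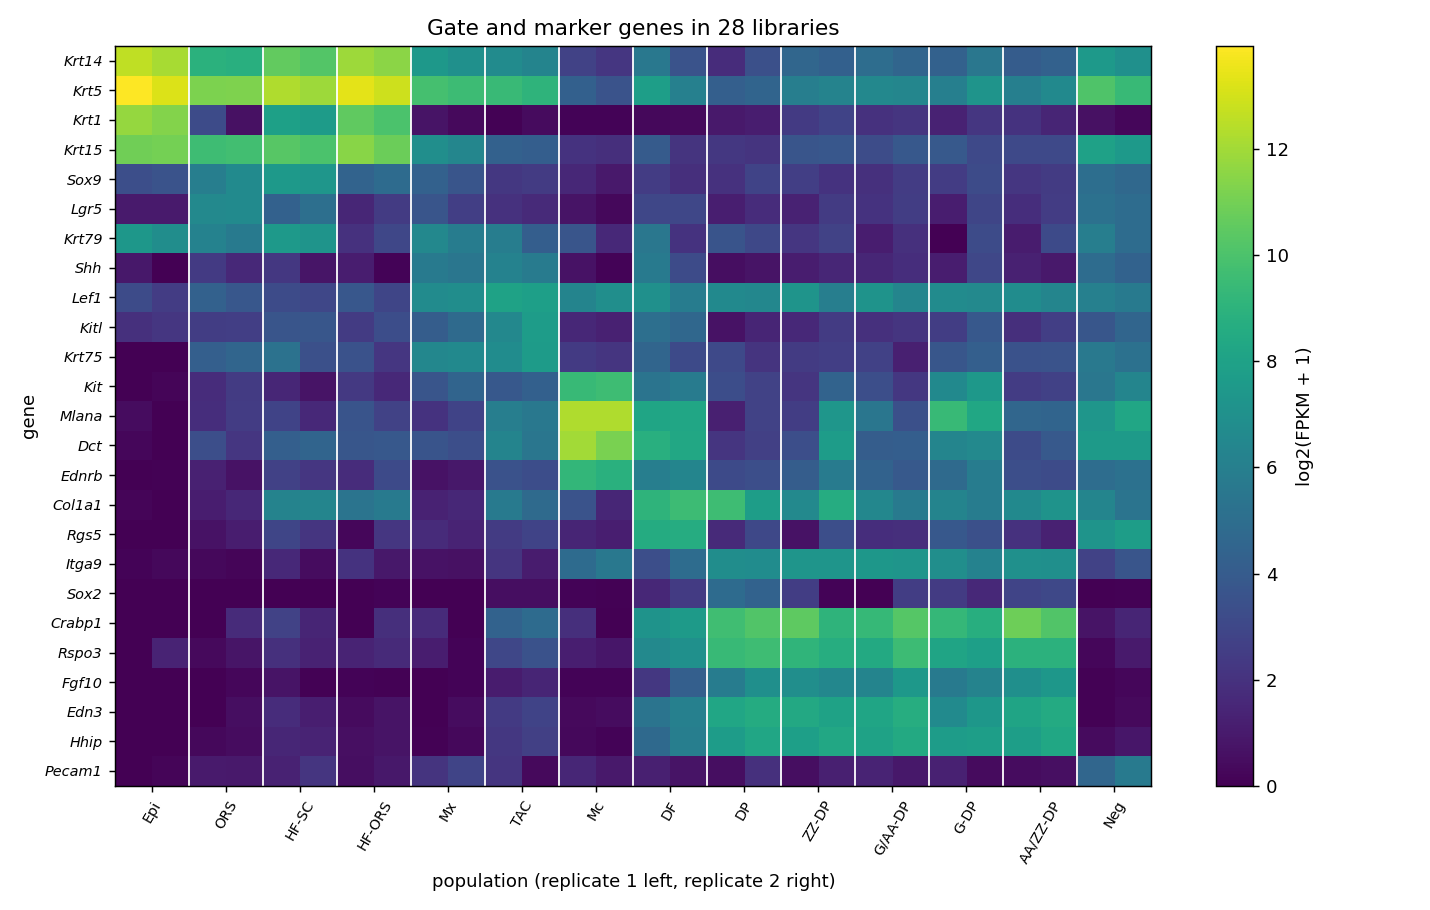
Level of gate and marker genes, as log2(FPKM + 1) on a colour scale that starts at 0, in each of the 28 libraries, with genes in rows and the 2 replicates of each population side by side. Krt14 averaged 5375 FPKM in Epi and 4.67 FPKM in Mc, Mlana 5036 FPKM in Mc, and Rspo3 725 FPKM in DP.

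The 8 populations of the K14-H2BGFP line were first compared with one another to find which genes, and which signalling genes, set each apart. Dermal papilla cells were set apart by secreted growth factors. Rspo3, an agonist of Wnt signalling, averaged 725 ± 86.4 in DP and 110 ± 24.3 in DF, the next highest population. Fgf7, which acts on keratinocytes, averaged 468 ± 309.9 in DP and 67.1 ± 58.4 in DF. Edn3, a melanocyte growth factor, averaged 344 ± 58.0 in DP and 53.5 ± 18.2 in DF. Epidermis was set apart by suprabasal keratins, with Krt1 at 3038 ± 559 and Krt10 at 3191 ± 877 against 4.26 ± 5.24 and 5.88 ± 2.54 in ORS. Melanocytes were set apart by Mlana (5036 ± 5.06), the neuropeptide gene Npy (2061 ± 574) and the melanocortin receptor gene Mc1r (385 ± 58.4).

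Signature genes, called higher in a population than in each of the other 7, numbered 288 in Epi, 31 in ORS, 1 in Mx, 29 in TAC, 470 in Mc, 47 in DF, 273 in DP and 104 in Neg. Of 118 signalling ligands tested, 13 were DP signature genes against 2.1 drawn at random (odds ratio 6.98, Fisher's exact test, two-sided, adjusted p = 3.52e-06 over 16 tests). They included Rspo4, Fgf10, Rspo2, Vegfa, Ndp, Bmp6 and Gdf10. Epi held 11 ligands against 2.3 (adjusted p = 0.00013), among them Ccl27a, Figf and Wnt16 and 4 more Wnt genes, Wnt7b, Wnt4, Wnt7a and Wnt3a. Of 119 receptors, 7 were DP signature genes (adjusted p = 0.0239), among them Mc5r, Dcc, Unc5c, Lepr, Gfra1 and Fgfr1. Neg held 6 receptors (Flt4, Aplnr, Kdr, Tie1, Robo4 and Csf1r, adjusted p = 0.000928), of which Flt4, Kdr and Tie1 are known from endothelium. With small RNAs, predicted names and joined rows left out, as in all signatures, the largest changes in Neg were those of the haemoglobin gene Beta-s (525 ± 107), the vascular gene Lyve1 (67.3 ± 18.3), Flt4, Mmrn1 and Cdh5 (34.3 ± 11.6), an endothelial cadherin gene. The Mc signature held 7 receptors, Mc1r, Kit, Plxnc1, Ednrb, Met, Plxna4 and Erbb4, and 2 ligands, Vegfc and Sema3b. Neither count passed the test, with adjusted p = 0.233 for receptors and 0.946 for ligands.

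The ORS signature was led by Krt19, Fgf5, Aldh3a1, Piwil2 and Il31ra, and held the ligand gene Sema3e and the receptor genes Vdr and Ret (adjusted p = 0.0661 for 2 ligands and for 2 receptors). Krt19 averaged 14.1 ± 0.73 in ORS and 1.65 ± 1.90 in Neg. Neg, the next highest population for most ORS signature genes, held keratinocyte RNA, with Krt5 at 888.5 ± 289.2 against 840.3 ± 108.2 in Mx. Lgr5 was at 32.7 ± 3.81 in Neg and 97.8 ± 5.44 in ORS, and the melanocyte gene Mlana at 232 ± 98.7 in Neg. An ORS gene also present in Neg can therefore miss the signature. The TAC signature was led by Foxq1 (59.6 ± 9.35), Tgm6 (84.4 ± 19.2), Sptssb, Uox and Aldh1a3. It held 1 ligand, the Kit ligand gene Kitl, at 150 ± 87.3 in TAC and 29.2 ± 6.48 in DF (adjusted p = 0.363). DF was led by Gpr17, Cysltr2, Adam23, Prokr2 and Scn7a and held none of the ligands or receptors. Schwann cell markers had mean log2 levels of 3.45 and 3.56 in the DF libraries and of 1.71 and 2.25 in Neg. Signature genes of DF need therefore not be genes of fibroblasts. The 1 Mx gene was Tal2, higher than in Neg by a log2 change of 1.72, which was named after its values were seen. Both Mx and TAC were sorted as dim GFP cells, so a gene at like levels in both cannot enter either signature. Their counts are therefore not comparable with the others. Epi held 1 receptor, Bmpr1b, and Neg 2 ligands, Il6 and Il1b, and neither number passed. Among the genes given here, Fgf7, Bmp6, Gdf10, Lepr, Gfra1 and Fgfr1 of DP, Npy, Met, Plxna4, Erbb4, Vegfc and Sema3b of Mc, Figf, Wnt7a, Wnt3a and Bmpr1b of Epi and Foxq1, Sptssb, Aldh1a3 and Kitl of TAC lost their place in the signature with at least 1 library left out. So did Krt19, Fgf5, Aldh3a1, Piwil2, Sema3e, Vdr and Ret of ORS, Cysltr2 and Scn7a of DF and Aplnr, Il6 and Il1b of Neg. With a pseudocount of 0.1, Rspo3 and Ndp of DP and Il31ra of ORS also lost theirs, and with a pseudocount of 5 Csf1r of Neg. Leaving out 1 library moved 4 signature counts over 1.5 times besides Mx: DP to 114 without DF replicate 1 and 175 without DP replicate 1, and DF to 28 without Neg replicate 1. ORS moved to 14 and 12 without ORS replicates 1 and 2 and to 16 and 14 without Neg replicates 1 and 2, and TAC to 13 and 19 without Mx replicates 1 and 2.

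**Figure D2:**
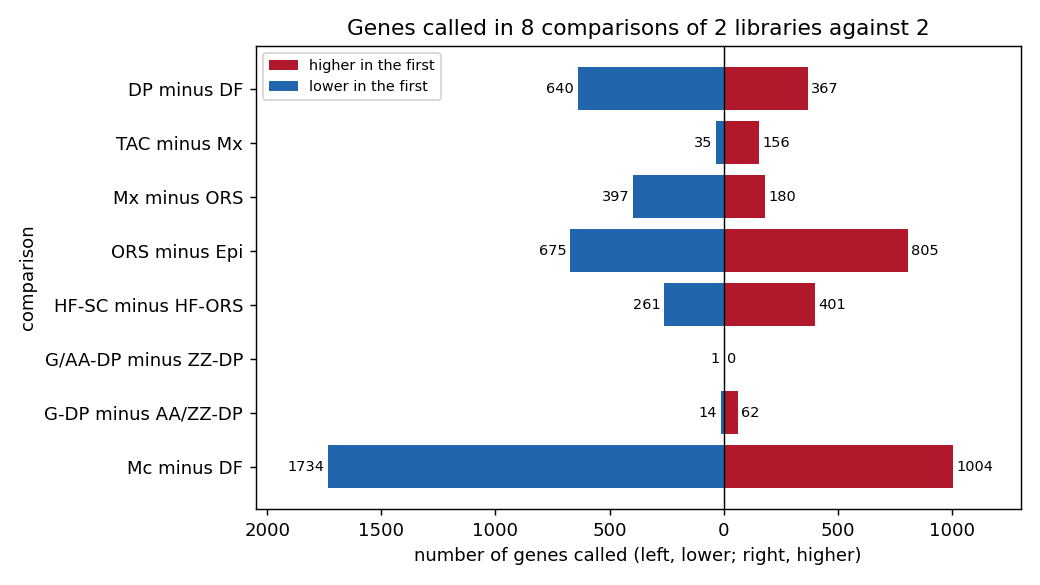
Number of genes called in each of the 8 pairwise comparisons, with bars to the right for genes higher in the first population and bars to the left for genes lower in it, on a linear axis from 0. The count ran from 1 between the Sox2-GFP sorts to 2738 between melanocytes and fibroblasts.

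The comparison of DP with DF asked what distinguishes the inductive cells of the follicle base from the surrounding fibroblasts. The gate gene Itga9 was higher in DP, at 111 ± 2.75 against 19.6 ± 14.5 (log2 change 2.65 ± 0.50, adjusted p = 0.00179), and Lef1 was at 92.1 ± 6.54 against 90.4 ± 48.5, without a call. Trpm3, encoding a cation channel, was at 72.0 ± 2.60 in DP and 3.73 ± 3.84 in DF (mm10 chromosome 19, 22137797 to 22995410; log2 change 4.24 ± 0.50, adjusted p = 2.52e-05). Snap91 was at 64.7 ± 1.07 against 3.34 ± 3.26 (chromosome 9, 86765923 to 86880734). Sostdc1, encoding a secreted inhibitor of BMP and Wnt signals, was at 853 ± 138 against 63.2 ± 60.6, and the coagulation factor gene F5 at 357 ± 33.0 against 28.8 ± 20.0. Lower in DP were Rgs5, a pericyte gene, at 4.66 ± 3.50 against 388 ± 3.09 (chromosome 1, 169655501 to 169695813; log2 change -6.26 ± 0.66, adjusted p = 7.28e-06), Ptgds, and the pigment genes Mlana and Dct.

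Of 28 dermal papilla genes, 15 were higher in DP, none was lower and 13 were not called, and adjusted over the list alone 21 were higher (camera adjusted p = 1.04e-19). They included Fgf10 (90.7 ± 46.8 against 10.6 ± 9.72), Rspo3 and Sox2 (24.6 ± 6.07 against 3.13 ± 1.75). Among 17 secreted Wnt modulators tested, 6 were higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.000132). Rspo4 was at 62.5 ± 45.7 against 4.20 ± 3.64, while Dkk2, a secreted Wnt antagonist, was at 4.35 ± 1.0 against 20.1 ± 11.9. Among 29 genes of BMP and TGF-beta signalling, 5 were higher and 1 was lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.000139, adjusted p = 0.0654 with an estimated correlation). Ltbp1, a binding protein of latent TGF-beta, was at 350 ± 19 against 62.7 ± 16.2, and Bmp6 at 72.3 ± 25 against 16.6 ± 2.17. Of 12 genes of Hedgehog reception 1, Hhip, was higher, at 260 ± 70.8 against 44.5 ± 25.6 (2 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.207 with an estimated correlation). Of 28 fibrous matrix genes, 3 were lower, Postn, Eln and Fn1, and 25 were not called (6 lower adjusted over the list alone, camera adjusted p = 0.00389, adjusted p = 0.384 with an estimated correlation).

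Markers of other cells stood beside these differences in DF. All 10 melanocyte markers were lower in DP than in DF (camera adjusted p = 7.23e-19), with Mlana at 300.3 ± 4.59 in DF and 3.56 ± 3.11 in DP. So were 10 of 12 keratinocyte markers (adjusted p = 6.63e-14), 9 of 13 smooth muscle and pericyte markers (adjusted p = 4.15e-15), 8 of 13 Schwann cell markers, 1 of which was higher (adjusted p = 3.7e-10), and 1 of 7 skeletal muscle markers (adjusted p = 0.00945). The 2 DF libraries differed in such genes, with Krt14 at 46.3 and 11 and Shh at 50.1 and 7.99. Papilla genes were present in DF as well, with Corin at 93.8 ± 14.0 against 422 ± 70.0 in DP and Sox2 at 3.13 ± 1.75 against 24.6 ± 6.07. Papilla cells in the DF sort would lessen the changes of such genes, and their presence was not tested. Markers of fibroblasts (2 of 12 lower, adjusted p = 0.139), endothelial cells (1 of 15 lower, adjusted p = 0.639), leukocytes, mast cells, adipocytes and erythroid cells did not pass the list test. In all, 1007 genes were called, 367 higher and 640 lower in DP, of which 59 were listed at 0 in both libraries of 1 population. Without signature genes of the other 6 populations 867 were left, 363 higher and 504 lower, a count chosen after seeing the data. These included Malat1, a nuclear non-coding RNA listed at 0 in both DP libraries and at 5645 and 9696 in DF. The count fell to 539 without DF replicate 1 and 605 without DP replicate 1, and 10 of 27 named calls, Itga9, Sox2, Crabp1, Kit, Krt14, Bmp6, Dkk2, Sfrp4, Eln and Postn, were lost when at least 1 library was left out. A further named call, of Bmp5, was lost with a pseudocount of 5 or quantile normalization, that of Crabp1 also with the replicate number as a block (adjusted p = 0.0523), and that of the skeletal muscle list with no filter on low values (0.137). Calls with a pseudocount of 0.1 were 184 higher and 562 lower in DP, so the higher ones fell more. The fibrous matrix list lost its call without DF replicate 2 (adjusted p = 0.924) or DP replicate 2 (0.19), Hedgehog reception without DP replicate 1 (0.0561) or DF replicate 2 (0.0735), and skeletal muscle without DP replicate 2 (0.0969), while the fibroblast markers passed as lower without DF replicate 1 (0.0047) or DP replicate 1 (0.0202).

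Melanocytes were set against fibroblasts, both sorted as Lef1-RFP-positive, the first with and the second without CD117. The gate gene Kit was at 734 ± 71.0 in Mc and 47.8 ± 10.8 in DF (mm10 chromosome 5, 75574987 to 75656722; log2 change 3.93 ± 0.56, adjusted p = 3.04e-05). Slc7a11, encoding the cystine transporter used in pheomelanin synthesis, was at 269 ± 230 against 8.25 ± 10.9. Npy, the peptide transporter gene Slc15a1, Lmo2 (159 ± 108 against 5.02 ± 3.93) and Syngr1 were also higher. Fibrillar collagen Col3a1 was at 7.39 ± 2.95 in Mc and 1595 ± 1079 in DF (chromosome 1, 45311538 to 45349706; log2 change -7.43 ± 0.44), and Rgs5, Col6a2, Lum and Thy1 were lower by log2 changes of -7.29 to -6.83.

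Of 24 melanocyte and pigment genes tested, 22 were higher in Mc, none was lower and 2 were not called (23 higher adjusted over the list alone, camera adjusted p = 3.01e-15, adjusted p = 0.0733 with an estimated correlation). Slc45a2, a transporter of pigment granules, was at 1191 ± 407 against 70.5 ± 32.9. The shorter list of 10 melanocyte markers held 9 of higher level (adjusted p = 1.54e-07, adjusted p = 0.0995 with an estimated correlation). All 12 fibroblast markers (adjusted p = 9.5e-21) and all 13 smooth muscle and pericyte markers (adjusted p = 3.01e-15) were lower in Mc. Keratinocyte markers were lower in 10 of 12 cases with Cdh1 higher (adjusted p = 2.47e-07, adjusted p = 0.0995 with an estimated correlation), Schwann cell markers in 7 of 13 with Sox10 higher (0.00129, and adjusted p = 0.0668 with an estimated correlation), and skeletal muscle markers in 3 of 7 (0.0311, and adjusted p = 0.0995 with an estimated correlation). The other marker lists did not pass. Overall counts were 1004 genes higher and 1734 lower, 2738 in all, with 273 listed at 0 in both libraries of 1 population. The skeletal muscle list lost its call without DF replicate 1 (adjusted p = 0.0888) or Mc replicate 2 (0.0537), and of 17 named calls Krt14 and Sox2 were lost when at least 1 library was left out. Npy lost its call with a pseudocount of 0.1, Sox2 also with the replicate number as a block (adjusted p = 0.0682), and the skeletal muscle list with quantile normalization (0.0685), no filter (0.123) or a filter at 5 FPKM (0.0615).

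ORS and Epi contrasted keratinocytes of the follicle's outer layer with those of the surface epidermis. Slc7a8, an amino acid transporter gene, was at 145 ± 14.0 in ORS and 0.13 ± 0.04 in Epi (mm10 chromosome 14, 54722215 to 54781886; log2 change 7.01 ± 0.45, adjusted p = 1.69e-09). Fstl1, the gap junction gene Gjb2, Myl9 and Col14a1 were higher in ORS by log2 changes of 6.32, 6.31, 6.08 and 5.67. Krt1 (chromosome 15, 101845426 to 101850786) was lower in ORS, with a log2 change of -9.66 ± 0.52 (adjusted p = 3.08e-10), as were Krt10, the cystatin gene Stfa3, Npl and Sprr4, the last listed at 0 in both ORS libraries and at 153 and 69.4 in Epi. Krt14 was at 463 ± 29.5 in ORS and 5375 ± 1257 in Epi, and Sox9, a transcription factor of follicle stem cells, at 80.5 ± 28.4 against 9.92 ± 1.21 (log2 change 2.86 ± 0.38, adjusted p = 1.82e-05).

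Among 22 epidermal differentiation genes tested, 15 were lower in ORS, none was higher and 7 were not called (16 lower adjusted over the list alone, camera adjusted p = 1.3e-17). The 28 bulge stem cell genes divided into 12 higher, 6 lower and 10 not called (14 and 6 adjusted over the list alone, camera adjusted p = 0.00055). Lgr5, a receptor for R-spondins, was at 97.8 ± 5.44 in ORS and 1.02 ± 0.02 in Epi, and Lhx2 at 131 ± 46.5 against 6.21 ± 6.41. Postn and Col17a1 were lower, Col17a1 at 108 ± 1.53 against 579 ± 67.5. The 23 hemidesmosome and basement membrane genes went both ways, with 7 higher and 4 lower (7 and 7 adjusted over the list alone, median log2 change -0.13, mean 0.18, camera adjusted p = 0.897). The collagen IV gene Col4a1 (71.5 ± 14.0 against 3.65 ± 2.29) and the laminin gene Lamb1 were higher, and Col7a1 of anchoring fibrils lower. Upper follicle and sebaceous genes also went both ways, with 4 of 19 higher, including Sox13 and Prdm1, and 4 lower, including Ly6a and Klk10 (5 and 4 adjusted over the list alone, camera adjusted p = 0.37). None of 30 cell cycle genes was called, singly or adjusted over the list alone, although the list passed as higher (median log2 change 0.93, camera adjusted p = 5.74e-05, adjusted p = 0.343 with an estimated correlation). Rrm1 was at 52.3 ± 2.81 against 24.7 ± 0.26.

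Smooth muscle and pericyte markers were higher in ORS in 6 of 13 cases and lower in 1 (adjusted p = 0.000243, adjusted p = 0.142 with an estimated correlation), led by Acta2 and Tagln. Keratinocyte markers were lower in 5 of 12 (0.00011, and adjusted p = 0.322 with an estimated correlation). Endothelial (2 of 15, 0.00931), fibroblast (2 of 12, 0.036) and erythroid (2 of 5, 0.0408) markers were higher, with adjusted p = 0.24, 0.343 and 0.221 with an estimated correlation. The remaining marker lists did not pass. The comparison called 1480 genes, 805 higher and 675 lower in ORS, with 123 listed at 0 in both libraries of 1 population. Without ORS replicate 2 the count was 947, and of 25 named calls Kit and Klk10 were lost when at least 1 library was left out. The fibroblast list lost its call without Epi replicate 2 (adjusted p = 0.0928) or ORS replicate 2 (0.0695), and the erythroid list without ORS replicate 1 (0.224) or Epi replicate 2 (0.154). With a pseudocount of 5 the fibroblast (0.313), endothelial and erythroid (both 0.0819) lists lost theirs, and with quantile normalization the fibroblast list (0.0604). With the replicate number as a block Lef1, Rrm1 and Bub1b were called higher in ORS (adjusted p = 0.00976, 0.00906 and 0.0411), and the erythroid list lost its call (0.0775).

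Mx and ORS contrasted the matrix progenitors of the hair bulb with the outer root sheath. Shh, the Hedgehog ligand gene, was at 47.9 ± 5.19 in Mx and 3.08 ± 1.41 in ORS (log2 change 3.62 ± 0.67, adjusted p = 0.00255), and Lef1, a transcription factor of Wnt signalling, at 110 ± 6.61 against 16.3 ± 4.52. Krt35, a hair shaft keratin gene, was at 117 ± 21.2 against 3.32 ± 2.09 (mm10 chromosome 11, 100092192 to 100096224; log2 change 4.86 ± 0.74, adjusted p = 0.000459). Prr9, Krt73, Wnt10b (20.6 ± 6.45 against 0.58 ± 0.27) and Sp6 were also higher in Mx. Lgr5 was at 8.32 ± 4.59 in Mx and 97.8 ± 5.44 in ORS (chromosome 10, 115450314 to 115587780; log2 change -3.50 ± 0.52, adjusted p = 0.000418), and Thy1, Cdo1, Col12a1 and Acta2 were lower by log2 changes of -3.89 to -3.62.

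Of 24 matrix progenitor regulators, 10 were higher in Mx, none was lower and 14 were not called (19 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.38e-18). Of 14 inner root sheath genes tested, 9 were higher (10 adjusted over the list alone, camera adjusted p = 1.26e-15), with Krt25 at 836 ± 2.61 against 83.3 ± 20.4. Hair shaft keratins and cuticle genes were higher in 4 of 15 cases, with Dsg4 at 30.7 ± 10.7 against 3.02 ± 1.76 (5 adjusted over the list alone, camera adjusted p = 6.97e-05, adjusted p = 0.0608 with an estimated correlation). Hemidesmosome and basement membrane genes were lower in 13 of 23 cases and higher in none (16 lower adjusted over the list alone, camera adjusted p = 6.72e-19). Col4a1 was at 9.21 ± 6.42 against 71.5 ± 14.0, and Egfl6 at 0.91 ± 0.73 against 13.7 ± 10.2. Bulge stem cell genes were lower in 15 of 28 cases, including Sfrp1 (14.6 ± 8.02 against 135 ± 25.2) and Sox9 (15.4 ± 5.16 against 80.5 ± 28.4), while Aldh1a3 and Wif1 were higher (2 higher and 16 lower adjusted over the list alone, camera adjusted p = 9.28e-18). None of the 30 cell cycle genes was called in limma, also adjusted over the list alone (camera adjusted p = 0.79), and Pcna was at 214 ± 8.08 against 168 ± 6.09. Smooth muscle and pericyte markers were lower in Mx in 6 of 13 cases, with Notch3 higher (adjusted p = 0.000365, adjusted p = 0.0934 with an estimated correlation), and no other marker list passed.

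This contrast called 577 genes, 180 higher and 397 lower in Mx, with 10 listed at 0 in both libraries of 1 population. The count was 320 without ORS replicate 1, 230 without ORS replicate 2 and 193 without Mx replicate 2. Of 21 named calls 7 were lost when at least 1 library was left out, those of Shh, Itga6, Thy1, Col12a1, Wif1, Dsg4 and Egfl6, and the hair shaft list lost its call without ORS replicate 1 (adjusted p = 0.0788). With the replicate number as a block Kit was called higher in Mx (adjusted p = 0.0335).

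TAC, the Lef1-RFP-positive part of the dim GFP gate, was set against Mx as a whole. Prdm1, a transcriptional repressor gene, was at 72.9 ± 37.3 in TAC and 9.25 ± 2.78 in Mx (mm10 chromosome 10, 44437174 to 44528558; log2 change 2.78 ± 0.32, adjusted p = 0.000193). The keratin gene Krt15 was at 18.0 ± 1.10 against 101 ± 25.3 (chromosome 11, 100131759 to 100135949; log2 change -2.40 ± 0.42, adjusted p = 0.00463), and Sox9 at 4.13 ± 0.39 against 15.4 ± 5.16. Fgfbp1, Barx2, Apobec1 and Lurap1l were also lower in TAC. The 5 largest higher changes were in Sct (63.7 ± 53.3 against 2.51 ± 1.19), the matrix genes Lum, Col1a1 and Col3a1, and Crabp1, with Col3a1 at 71.2 ± 1.21 against 4.80 ± 1.05 (log2 change 3.65 ± 0.44, adjusted p = 0.000193). Neither Lef1 (245 ± 18.3 against 110 ± 6.61, adjusted p = 0.287) nor Shh (62.7 ± 11 against 47.9 ± 5.19, adjusted p = 1) was called.

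Fibroblast markers stood beside these differences. Of 12, 6 were higher in TAC (11 adjusted over the list alone, camera adjusted p = 2.56e-17), among them Lum, Col1a1 and Col3a1. None of the 10 melanocyte markers was called singly (9 higher adjusted over the list alone, camera adjusted p = 6.48e-10, adjusted p = 0.125 with an estimated correlation), with Mlana at 53.6 ± 9.54 against 4.5 ± 2.04. Keratinocyte markers were lower in 1 of 12 cases, Krt15 (adjusted p = 0.00943, adjusted p = 0.443 with an estimated correlation), and the other marker lists did not pass. Among 15 hair shaft and cuticle genes tested, Krt36 was higher, at 4.45 ± 0.96 against 0.46 ± 0.42 (3 adjusted over the list alone, median log2 change of the list 1.29, camera adjusted p = 6.44e-08). Of 24 matrix progenitor regulators, Prdm1 was higher (3 adjusted over the list alone, camera adjusted p = 0.00294, adjusted p = 0.396 with an estimated correlation). Of 14 inner root sheath genes, Padi1 was higher (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.797), and of 18 Notch signalling genes, Hey2 (also 1 adjusted over the list alone, camera adjusted p = 0.105), listed at 0 and 0.11 in Mx and at 4.20 and 2.16 in TAC. None of 30 cell cycle genes was called, also adjusted over the list alone, while the list passed as lower (median log2 change -0.63, camera adjusted p = 7.12e-08, adjusted p = 0.396 with an estimated correlation), with Mcm3 at 24.9 ± 5.41 against 56.2 ± 3.12.

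The comparison called 191 genes, 156 higher and 35 lower in TAC, with 8 listed at 0 in both libraries of 1 population. Crabp1 and Hey2 were also DP signature genes, and without signature genes of the other 6 populations, a count chosen after seeing the data, 151 were left, 122 higher and 29 lower. With the replicate number as a block 336 were called, 256 higher and 80 lower, among them Mcm3 as lower (adjusted p = 0.022). Leaving out Mx replicate 1 or 2 gave 51 or 61 calls and leaving out TAC replicate 1 or 2 gave 80 or 85, quantile normalization gave 121, and of 15 named calls those of Col3a1 and Prdm1 alone were kept with each library left out. Keratinocyte markers lost their call with quantile normalization (adjusted p = 0.0621) and without TAC replicate 2 (adjusted p = 0.0878), which made the Notch list pass (0.0152), while endothelial (0.00369) and erythroid (0.0161) markers passed as lower without TAC replicate 1.

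HF-SC and HF-ORS asked how precursors of bulge stem cells differ from the rest of the outer root sheath. The gate gene Sox9 was at 172 ± 14.5 in HF-SC and 24.9 ± 5.55 in HF-ORS (mm10 chromosome 11, 112782210 to 112787757; log2 change 2.76 ± 0.38, adjusted p = 0.000126). Krt79, a keratin gene of the upper follicle, was at 162 ± 19.3 against 4.84 ± 2.62 (chromosome 15, 101929332 to 101940324; log2 change 4.88 ± 1.0, adjusted p = 0.00611). Tgfb2 was at 54.5 ± 5.39 against 2.48 ± 2.03 (log2 change 4.13 ± 0.41, adjusted p = 3.7e-06), and Adamts17 and Abi3bp were higher as well, with Krtap17-1 listed at 0 in both HF-ORS libraries and at 16.6 and 26.9 in HF-SC. H19, an imprinted non-coding RNA, was at 107 ± 17.2 in HF-SC and 1858 ± 547 in HF-ORS (chromosome 7, 142575530 to 142578146; log2 change -4.08 ± 0.51), and Gdpd2 was lower. Filip1l, Zc3h7a and Guca2a were listed at 0 in both HF-SC libraries, which can be failed estimates. H19, Gdpd2 and Guca2a were also signature genes of Epi. Over 238 Epi signature genes the HF-ORS libraries lay at a median of 77.5% and 78.6% of the way from the ORS to the Epi level, and the HF-SC libraries at 30.8% and 27.9%.

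Of 28 bulge stem cell genes, 10 were higher in HF-SC, none was lower and 18 were not called (15 higher adjusted over the list alone, camera adjusted p = 2.23e-09), with Dkk3 at 65.1 ± 18.0 against 6.04 ± 2.80. The same list had 12 genes higher and 6 lower in ORS than in Epi. Lgr5 was at 26.0 in HF-SC and 3.16 in HF-ORS, between 97.8 in ORS and 1.02 in Epi. With HF-ORS nearer to Epi over Epi signature genes, precursors against sheath cannot be told apart here from sheath against epidermis. Upper follicle and sebaceous genes were higher in 6 of 19 cases (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.75e-07). The adipogenic and sebocyte regulator Pparg was at 4.63 and 36.1 in the HF-SC libraries, and at 0 and 0.07 in HF-ORS. BMP and TGF-beta signalling genes were higher in 6 of 29 cases and lower in 1, Bmp3 (12 and 1 adjusted over the list alone, camera adjusted p = 6.04e-06, adjusted p = 0.0711 with an estimated correlation), and Ltbp1 was at 39.5 ± 3.35 against 1.84 ± 1.64. Secreted Wnt modulators were higher in 2 of 17 cases, Sostdc1 (423 ± 131 against 40.7 ± 24.5) and Dkk3 (2 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.233 with an estimated correlation). Of 22 epidermal differentiation genes, 4 were lower, including the Epi signature gene Krt1 (220 ± 25 against 1253 ± 323) and Tgm3, and Abca12 was higher (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.122). None of 23 hemidesmosome and basement membrane genes (camera adjusted p = 0.74) or 30 cell cycle genes (0.947) was called in limma, also adjusted over the list alone. Egfl6 was at 25.9 ± 11 against 4.21 ± 0.63, and Mcm7 at 41.8 ± 10.8 against 23.6 ± 4.34.

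Endothelial (1 of 15 higher, adjusted p = 0.0339), adipocyte (2 of 6 higher, 0.043) and mast cell markers (none of 7 called, lower as a list, 0.043) passed with the preset correlation, with adjusted p = 0.322, 0.264 and 0.454 with an estimated correlation, and no other marker list passed. Among those not passing, 3 of 13 leukocyte markers were lower in HF-SC (camera adjusted p = 0.294) and 1 of 13 Schwann cell markers was higher (0.602). In total 662 genes were called, 401 higher and 261 lower in HF-SC, with 35 listed at 0 in both libraries of 1 population. Of the lower genes 80, and of the higher genes 5, were Epi signature genes, and without these 577 were called, 396 higher and 181 lower, a count chosen after seeing the data. With the replicate number as a block 1125 were called, 619 higher and 506 lower, among them Egfl6 as higher and Fras1 as lower (adjusted p = 0.00498 and 0.0193), while the endothelial (0.0831), adipocyte and Wnt modulator (both 0.0643) and mast cell (0.0873) lists lost their calls. These 4 lists also lost them with a pseudocount of 5 (0.0686 to 0.0714). The count was 316 without HF-ORS replicate 1 and 396 without HF-SC replicate 2, and of 19 named calls Krt79, Krt1, Sostdc1 and Abca12 were lost when at least 1 library was left out. The endothelial and adipocyte lists lost their calls without any 1 of the 4 libraries (adjusted p from 0.0526 to 0.132 and from 0.0548 to 0.152), the mast cell list without HF-SC replicate 2 (adjusted p = 0.258) or HF-ORS replicate 2 (0.885), and the Wnt modulators without HF-SC replicate 2 (0.16) or HF-ORS replicate 2 (0.145).

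**Figure D3:**
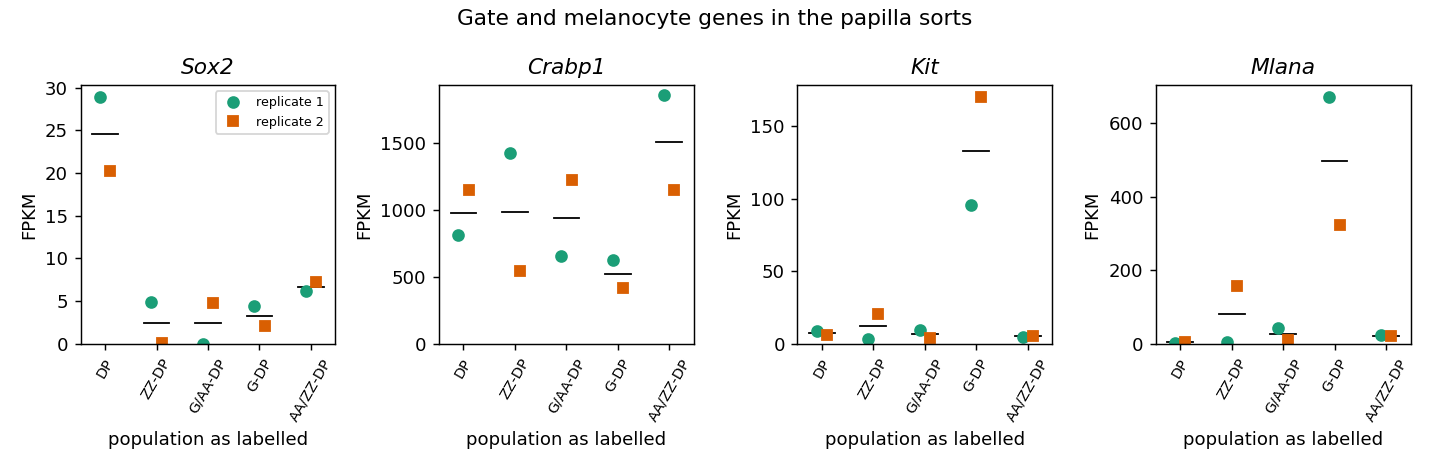
Level in FPKM (linear axes from 0) of the gate genes Sox2, Crabp1 and Kit and the melanocyte gene Mlana in the 5 papilla sorts, as labelled. Each point is 1 library and the line is the mean of 2. Sox2 was at 4.87 and 0.09 in the libraries labelled ZZ-DP and at 0 and 4.81 in those labelled G/AA-DP, and Kit averaged 133 in G-DP.

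The Sox2-GFP reporter was used to compare papillae of guard and awl/auchene follicles with those of zigzag follicles. Sox2 itself went against the labels in replicate 1. It was at 4.87 in the library labelled ZZ-DP replicate 1, sorted as Sox2-GFP-negative, and listed at 0, which can be a failed estimate, in the library labelled G/AA-DP replicate 1, while in replicate 2 the values were 0.09 and 4.81 (mm10 chromosome 3, 34649995 to 34652461). Crabp1 was at 1426 and 545 in the libraries labelled ZZ-DP and at 655 and 1227 in those labelled G/AA-DP. Every direction in this comparison therefore holds for the libraries as labelled.

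In limma 1 gene was called, with 211 at an unadjusted p under 0.05. It was Snora44, a small nucleolar RNA named after its values were seen, which was listed at 0 in both libraries labelled G/AA-DP and at 241 and 700 in those labelled ZZ-DP, so that the call rests on values that can be failed estimates. No member of the 7 pathway lists was called. The 28 fibrous matrix genes were lower as a list in the libraries labelled G/AA-DP (3 lower adjusted over the list alone, camera adjusted p = 3.36e-15, adjusted p = 0.102 with an estimated correlation), with Ogn at 0.83 ± 0.65 against 9.94 ± 6.59 and Dpt at 1.10 and 3.79 against 7.22 and 97.9. Hedgehog reception (12 genes, camera adjusted p = 0.92), secreted Wnt modulators (17, 0.441), BMP and TGF-beta signalling (29, 0.762), FGF signalling (24, 0.57), IGF signalling (18, 0.954) and Notch signalling (18, 0.57) did not pass, and 0 of their members passed adjusted over the list alone. Markers of melanocytes and fibroblasts (both adjusted p = 5.34e-06) and of smooth muscle and pericytes (0.0196) were lower as lists in the libraries labelled G/AA-DP. With an estimated correlation these gave adjusted p = 0.324, 0.151 and 0.36.

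The library labelled ZZ-DP replicate 2 carried much of that difference, with Col1a1 at 402 and Dct at 208 against 94.1 and 9.02 in replicate 1. Without it the fibrous matrix, fibroblast and smooth muscle lists lost their calls (adjusted p = 0.128, 0.476 and 0.176), and the melanocyte markers were higher in the libraries labelled G/AA-DP (median log2 change 0.90, adjusted p = 1.07e-07). Without the library labelled G/AA-DP replicate 2 the fibroblast (adjusted p = 0.0518), melanocyte and smooth muscle (both 0.196) lists lost theirs, and without that labelled G/AA-DP replicate 1 the smooth muscle list did (0.144) while BMP and TGF-beta signalling passed as lower (0.0218). Adipocyte markers passed as lower without the library labelled G/AA-DP replicate 1 (0.0095) or ZZ-DP replicate 2 (0.0288). The number of genes called was 15 without the library labelled ZZ-DP replicate 1 and 5 without the library labelled G/AA-DP replicate 2, and 4 with no filter on low values. The smooth muscle list also lost its call with no filter (0.0812) or quantile normalization (0.0726). A block for the replicate number gave 1 call.

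The Crabp1-GFP reporter was used to compare papillae of guard follicles with those of awl/auchene and zigzag follicles. Crabp1 was at 525 ± 148 in G-DP and 1508 ± 506 in AA/ZZ-DP (log2 change -1.51 ± 0.72, adjusted p = 0.597, not called). Kit was at 133 ± 52.7 in G-DP and 4.98 ± 0.68 in AA/ZZ-DP (log2 change 4.43 ± 0.56, adjusted p = 0.000317). The pigment transporter gene Slc45a2 was at 179 ± 54.5 against 4.40 ± 0.98 (mm10 chromosome 15, 11000721 to 11029233), and Mc1r at 53.8 ± 0.37 against 1.26 ± 0.38 (chromosome 8, 123407082 to 123410744). Npy and Lmo2 were also higher, and Rn45s, a ribosomal RNA precursor, was at 23369 and 1363 in G-DP and listed at 0, which can be a failed estimate, in the other 26 libraries. Of these higher genes, Kit, Slc45a2, Mc1r, Npy and Lmo2 were also Mc signature genes. Lower in G-DP were Tmem218 (6.15 ± 5.48 against 35.5 ± 1.86), Zfp804b, Alkbh2 and the transcription factor gene Tbx5.

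Of 10 melanocyte markers, 7 were higher in G-DP and none was lower (10 higher adjusted over the list alone, camera adjusted p = 7.58e-27). Beside them, 2 of 13 Schwann cell markers were higher, including Sox10, which is also a melanocyte gene (adjusted p = 0.0181, adjusted p = 0.326 with an estimated correlation). Of 24 FGF signalling genes, Etv5 (106 ± 6.32 against 26.9 ± 7.58) and Dusp6 (16.7 ± 3.83 against 4.97 ± 1.40), which respond to receptor kinase signals, were higher, Etv5 being also a signature gene of Mc (2 adjusted over the list alone, camera adjusted p = 0.991). No member of the other pathway lists was called. Fibrous matrix genes (adjusted p = 0.0146, adjusted p = 0.575 with an estimated correlation) and BMP and TGF-beta signalling genes (0.0181, and adjusted p = 0.399 with an estimated correlation) were lower as lists, with Mfap4 at 70.3 ± 13.4 against 170.4 ± 2.14. Secreted Wnt modulators (adjusted p = 0.108), Hedgehog reception (0.584), IGF signalling (0.907) and Notch signalling (0.701, with 1 gene, Heyl, higher adjusted over the list alone) did not pass. Sfrp2 was at 29.9 ± 6.19 against 151 ± 7.04 without a call. None of 12 keratinocyte, 15 endothelial or 13 smooth muscle and pericyte markers was called, but these lists passed as higher (adjusted p = 0.0021, 0.0143 and 0.00468), with adjusted p = 0.451, 0.326 and 0.326 with an estimated correlation.

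The comparison called 76 genes, 62 higher and 14 lower in G-DP, 8 of them listed at 0 in both libraries of 1 population. Of the 76, 34 (20 higher and 14 lower) were left once signature genes of Epi, ORS, Mx, TAC, Mc, DF and Neg were not counted, a count chosen after seeing the data. The number called was 282 without G-DP replicate 1, 29 without G-DP replicate 2, 49 without AA/ZZ-DP replicate 1, 13 without AA/ZZ-DP replicate 2 and 28 with a pseudocount of 0.1, and of 12 named calls those of Kit, Lmo2, Mc1r and Rn45s alone were kept with each library left out. Of the lists, the melanocyte markers alone kept their call with each of the 4 libraries left out. Without G-DP replicate 1 the fibrous matrix (adjusted p = 0.425), endothelial and Schwann cell (both 0.102) and smooth muscle (0.116) lists lost theirs, and without G-DP replicate 2 the BMP and TGF-beta (0.879), keratinocyte (0.63) and Schwann cell (0.0753) lists. Without AA/ZZ-DP replicate 1 the BMP and TGF-beta (0.529), endothelial (0.0671), keratinocyte (0.0963) and Schwann cell (0.0948) lists did, and without AA/ZZ-DP replicate 2 the fibrous matrix list (0.536). The BMP and TGF-beta list also lost its call with a pseudocount of 0.1 (0.0705) and the Schwann cell list with one of 5 (0.0506). A block for the replicate number gave 99 calls, while Zfp804b (adjusted p = 0.0547), Alkbh2 (0.0539) and the Schwann cell list (0.0652) were not called with it. No gene was called in limma in the same direction in both papilla comparisons, which says little, since the Sox2-GFP sorts had 1 call. At an unadjusted p under 0.05 in both, 14 genes had the same direction (9.1 for independent lists of these sizes) and 27 the opposite (8.6), a division that holds only for the Sox2-GFP libraries as labelled. Both comparisons share 1 spread per gene, so their lists are not independent and 9.1 and 8.6 are no exact reference. Melanocyte markers went opposite ways as a list, with median log2 changes of -0.91 in the Sox2-GFP sorts as labelled and 3.63 in G-DP minus AA/ZZ-DP. Genes of melanocytes may therefore be among the 27, which was not counted.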

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

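Leaving out libraries, pseudocounts, filters, scalings and the fit were all chosen before the results were seen, and the counts without signature genes of other populations or of Epi after. No named gene changed direction past its threshold under any of these. Median-of-ratios scaling and the fit without a trend moved no count of called or signature genes over 1.5 times. Neither scaling moved the share of higher among called genes by over 10 percentage points or the median of all genes by over 0.1 on the log2 scale. The deposited table may already have been scaled between libraries, so a small effect of median-of-ratios scaling is a weak check. For the moves below the cause was not tested, except where fewer libraries or genes entered. With a pseudocount of 0.1, G-DP minus AA/ZZ-DP had 28 calls, and the signatures of Epi 190, ORS 6, TAC 11, DF 19, DP 127 and Neg 54 genes. With a pseudocount of 5, DP minus DF had 668 and Mc minus DF 1695 calls, and the signatures of Mx 0, DF 31 and Neg 57. With no filter the libraries labelled G/AA-DP minus ZZ-DP had 4 calls and Mx 2 signature genes, and with a filter at 5 FPKM, which tests fewer genes, Mx had 0, DF 24 and Neg 48. Quantile normalization gave TAC minus Mx 121 calls. Leaving out signature genes of other populations gave G-DP minus AA/ZZ-DP 34. On the 4 libraries compared alone, which leaves 2 residual degrees of freedom, calls numbered 2 for DP minus DF, 0 for TAC minus Mx, 0 for Mx minus ORS, 742 for ORS minus Epi, 0 for HF-SC minus HF-ORS, 2 for the Sox2-GFP sorts as labelled, 2 for G-DP minus AA/ZZ-DP and 878 for Mc minus DF. Of the named calls, 26 of 27, 15 of 15, 21 of 21, 4 of 25, 19 of 19, 12 of 12 and 8 of 17 were lost there, in this order and with none to lose in the Sox2-GFP sorts. The size of these counts thus rests on the spread shared over 28 libraries. Signature counts, made on the 16 libraries of their line alone, stayed within 1.5 times, at 292 for Epi, 31 for ORS, 1 for Mx, 35 for TAC, 500 for Mc, 60 for DF, 344 for DP and 109 for Neg. List tests that had not passed did so in 6 cases with a pseudocount of 0.1, 2 with one of 5, 2 with no filter, 1 with quantile normalization and 7 on the libraries compared alone. Lists lost their call in 2 cases with a pseudocount of 0.1, 8 with one of 5, 5 with no filter, 2 with a filter at 5 FPKM and 5 with quantile normalization. On the libraries compared alone 6 did: adipocytes (adjusted p = 0.0809) and mast cells (0.113) in HF-SC minus HF-ORS, erythroid cells (0.0649) in ORS minus Epi, fibroblasts (0.0583) and melanocytes (0.116) in the Sox2-GFP sorts as labelled and Schwann cells (0.149) in G-DP minus AA/ZZ-DP.

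With 1 library left out, its population keeps a lone sample that is assumed to vary like the other groups. Calls then ran from 539 to 1023 for DP minus DF, 51 to 85 for TAC minus Mx, 193 to 409 for Mx minus ORS, 947 to 1070 for ORS minus Epi, 316 to 757 for HF-SC minus HF-ORS, 1 to 15 for the Sox2-GFP sorts as labelled, 13 to 282 for G-DP minus AA/ZZ-DP and 2011 to 2301 for Mc minus DF. Signatures ran from 215 to 278 for Epi, 12 to 33 for ORS, 0 to 2 for Mx, 13 to 37 for TAC, 348 to 447 for Mc, 28 to 69 for DF, 114 to 271 for DP and 71 to 105 for Neg, and shared papilla calls were 0, which so few Sox2-GFP calls all but fix. Between the libraries labelled G/AA-DP and ZZ-DP, the median log2 change of the melanocyte list ran from -2.78 to 0.90 and that of smooth muscle and pericytes from -0.62 to -0.007. Without ZZ-DP replicate 2 both list tests pointed the other way (adjusted p = 1.07e-07 and 0.176), although the second median stayed below 0.

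With the replicate number as a block, TAC minus Mx had 336 calls and HF-SC minus HF-ORS 1125, and the other total counts stayed within 1.5 times. The higher calls alone moved further in DP minus DF (from 367 to 578) and in Mx minus ORS (from 180 to 273). It changed no other call of a named gene or list than those given with the comparisons. Depth is unknown, so its limit on low genes cannot be stated.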

Other observations

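All tests in these observations, those of melanocyte and epidermal genes and of exchanged labels and dilution in the Sox2-GFP sorts, were chosen only after the result was seen.

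Several ligand genes and the genes of their receptors, chosen after their values were seen, had the following levels in the sorted populations. Shh was at 62.7 ± 11 in TAC and 47.9 ± 5.19 in Mx (mean FPKM ± SD, n = 2), and its receptor gene Ptch1 at 378 ± 17.9 in DP, 179 ± 49.3 in ORS and 175 ± 20.9 in DF, with the Hedgehog-binding protein gene Hhip at 260 ± 70.8 in DP and 0.15 ± 0.13 in Mx. Kitl was at 150 ± 87.3 in TAC and 1.15 ± 0.75 in DP, and Kit at 734 ± 71.0 in Mc. Edn3 was at 344 ± 58.0 in DP and Ednrb, encoding its receptor, at 530 ± 102 in Mc. Fgf7 and Fgf10 were at 468 ± 309.9 and 90.7 ± 46.8 in DP, while the receptor gene Fgfr2 was at 238 ± 12.5 in Epi, 244 ± 65.0 in TAC and 361 ± 27.1 in DP. Pdgfa was at 234 ± 77.3 in Epi and 10.4 ± 3.02 in DP, and Pdgfra at 147 ± 10.4 in DP and 72.5 ± 43.7 in DF. Lgr6 was at 90.6 ± 7.14 in HF-SC and 21.2 ± 1.37 in HF-ORS, Lgr5 at 26.0 ± 10.1 and 3.16 ± 1.81. No test was made of these pairs, and values per gene cannot separate splice forms of a receptor gene such as Fgfr2.

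Melanocyte genes were higher in G-DP than in AA/ZZ-DP, in a gate chosen for Lef1-RFP and high integrin alpha 9. Of 201 Mc signature genes at 50 FPKM or more in Mc, 86.1% and 83.1% lay above the AA/ZZ-DP mean in the 2 G-DP libraries, at a median excess of 6.33% and 9.89% of their Mc level, which is consistent with melanocyte RNA in both (Mlana at 670 and 321 FPKM, while 148 of the 201 genes also reached 5 FPKM in DP). A lower purity in general cannot be told apart from this, since in replicate 2 keratinocyte markers lay above AA/ZZ-DP by a median of 8.11% of their Mx level and melanocyte markers by 9.26% of their Mc level, while in replicate 1 these were 0.24% (quartiles -1.63 and 2.02) and 8.23% (2.84 and 11), and endothelial markers lay at 1.96% and 0.93% of their Neg level. Whether these were melanocytes in the state of the Mc sort cannot be told apart from other states, since the excess relative to Mc varied between 10 marker genes with a log2 SD of 1.43 and 0.87 in G-DP against 0.77 and 0.56 in DF, so that replicate 1 lay above the limit of 1.5 times the SD in DF for either DF library (ratios 1.86 and 2.55) and replicate 2 for only 1 of them (1.13 and 1.55). Melanocyte genes were not raised in the guard papilla sort alone. In the library labelled ZZ-DP replicate 2, 77.1% of the 201 genes lay above the G/AA-DP mean, at a median excess of 3.61% of their Mc level. In that labelled ZZ-DP replicate 1 these were 37.3% and -0.44%. G-DP and ZZ-DP were both sorted as GFP-negative. In Mc, Itga9 averaged 37.8 FPKM, while the reporter genes Crabp1 and Sox2 averaged 1.37 and 0.08. Guard follicle type therefore cannot be told apart from sorting as GFP-negative in G-DP. A difference between guard papillae and the others in contact with melanocytes may remain and was not tested.

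Sox2 was opposite to the label in replicate 1 of the Sox2-GFP sorts. Dilution of papilla RNA in the library labelled G/AA-DP replicate 1 is argued against, since 223 DP signature genes at 5 FPKM or more in DP had a median log2 ratio of -0.20 (quartiles -0.59 and 0.05) to the library labelled ZZ-DP replicate 1. An exchange of the labels in replicate 1 cannot be told apart from correct labels. The difference between the sorts correlated between replicates at -0.05 across 8601 genes, against 0.14 to 0.77 in the other 7 comparisons. Mc signature genes and genes called lower in DP than in DF were left out of these correlations. Crabp1 also changed its order between replicates, at 1426 and 545 in the libraries labelled ZZ-DP and 655 and 1227 in those labelled G/AA-DP, but 1 gene does not decide. The Sox2 value of 0 in the library labelled G/AA-DP replicate 1, on which the order of Sox2 rests, may be a failed estimate. In the other 7 papilla subtype libraries Sox2 was at 0.09 to 7.20 FPKM, against 28.9 and 20.3 in DP, so that chance may also set its order. Neither was tested.

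Epidermal genes were higher in HF-ORS than in the ORS sort of the other line. Of 238 Epi signature genes at 5 FPKM or more in Epi, 90 reached that in ORS too. Over the 238, HF-ORS libraries lay at a median of 77.5% and 78.6% of the way from ORS to Epi, and HF-SC libraries at 30.8% and 27.9%. Epidermal RNA in HF-ORS could give such values, and Krt10 was at 1075 ± 436 and H19 at 1858 ± 547 there, against 3191 ± 877 and 1947 ± 485 in Epi. Mx libraries lay at -0.8% and -1.7%, but these genes were selected as higher in Epi than in Mx, so Mx is no independent reference. The gate, bright K14-RFP with high integrin alpha 6, has no marker that would remove basal epidermis, but high integrin alpha 6 should remove suprabasal cells, which make Krt10, so the gate goes against these as the source. A difference of line or preparation shared by both Sox9-GFP sorts cannot be told apart as part of it, since the median log2 ratio of HF-SC to HF-ORS was -0.93 (quartiles -1.64 and -0.45). An epidermis-like state of part of the outer root sheath may contribute and was not tested.

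Malat1 was listed at 0 in all 10 papilla libraries and at 1734 to 9696 FPKM in the other 18, while Neat1, another nuclear RNA, had medians of 61.1 and 90.1. Zc3h7a and Filip1l were listed at 0 in both HF-SC libraries alone, and lay at 24.2 FPKM or more and 21.8 FPKM or more in the other 26. Of genes on the sex chromosomes, chosen after their values were seen, Ddx3y was at 1.89 to 5.06 FPKM in the 8 replicate 1 libraries of the K14-H2BGFP line and at 0 to 0.03 in the 8 replicate 2 libraries, and Xist was lower in replicate 1 in each of the 8 populations (176 to 506 against 299.8 to 868). In the K14-RFP Sox9-GFP line replicate 1 had Xist at 472 and 560 with Ddx3y at 0.02 and 0, and replicate 2 had Xist at 0.97 and 0.62 with Ddx3y at 25.3 and 19.2. In the Sox2-GFP line Xist was at 262 and 268 with Ddx3y at 10.8 and 7.95 in replicate 1, and at 0.45 and 0.36 with Ddx3y at 29.1 and 26.3 in replicate 2. In the Crabp1-GFP line Xist was at 0.36 to 0.45 and Ddx3y at 12.9 to 21.7 throughout.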
